A study of Mus musculus with 9 samples.

How the data were processed

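RNA was measured in the left tibialis anterior (TA), a fast-twitch muscle of the lower hind limb, of 13-month-old male mice. There were 3 wild-type (WT) mice, 3 mice labelled Svil-KO and 3 mice labelled Svil-Mut, each sequenced as 1 library. Per the labels' protocols, RNA was reverse-transcribed from an oligo(dT) primer and amplified as full-length cDNA with a SMARTer v4 low-input kit, and libraries were made by Nextera XT tagmentation. This kit does not mark strand, so reads from a gene and from an overlapping or antisense gene cannot be told apart. All 9 libraries carry the same batch label, 1. Groups were taken from the genotype label and replicate numbers from the titles, which number the WT and Svil-KO mice 1, 3 and 4 and the Svil-Mut mice 1, 2 and 4.

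Per the submitters' processing notes, the reads were processed with HISAT2, featureCounts and DESeq2 on the mm10 build. Their versions, settings and gene annotation are not given in the sources used here. The deposited table holds a signal per gene and library, the read count divided by a library size factor, for 56805 genes, and all of its sample columns were used. The values themselves showed this unit. In each library, all nonzero values (100%) were whole multiples of 1 step within 0.001, and the inverse of the steps equalled the median-of-ratios size factors. Multiplying by these factors recovered whole reads, 36234428 to 48762188 per library, with 19282 to 19988 genes detected. Dividing by size factors does not correct for transcript length or GC content. The normalization assumes that most genes do not differ between libraries, so a change shared by most genes would not be visible. No molecular identifiers are described, so reads are not independent molecules.

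Because the table holds normalized values, the main test was limma on log2(normalized count + 1), with genotype as the only factor, all 9 libraries in 1 fit and a mean-variance trend. Genes were tested if at least 3 libraries reached a normalized count of 10, which left 15279 genes. Fold changes are on this log2(value + 1) scale, which understates changes of genes with low counts. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The comparisons were Svil-KO against WT, Svil-Mut against WT and Svil-KO against Svil-Mut. The last of these is also the test of whether the effects of the 2 genotypes against WT differ.

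Gene lists were fixed before the data were examined, 32 for pathways and 10 for markers of cell types that a whole TA muscle can hold. They held 1148 entries of 1089 distinct genes, so some genes are in more than 1 list. They were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 42 lists within a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, were run beside it. Genes near Svil were those with midpoints within 10 Mb of the Svil midpoint on its chromosome, compared with all other tested genes by a 2-sided Fisher's exact test. Positions came from the GENCODE annotation of GRCm38, matched by symbol, and were found for 97.1% of the tested genes. This annotation need not be the one the authors counted on.

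Most genes named in the text follow a rule fixed at the same time as the gene lists. It takes Svil, and, where fewer than 10 genes pass in a comparison, the 10 genes with the smallest unadjusted p among genes whose libraries do not overlap between the genotypes, whose mean reaches 50 in the higher genotype and whose symbol is not that of a predicted gene. It also takes up to 4 members of each described list with the smallest p. Fewer than 10 genes passed in each of the 3 comparisons. In Svil-KO against WT, 1 gene that the rule takes is not reported here. Outside the rule, Gm9061, B4galt6 and the genes near Svil other than Mib1 and Kif5b were named after their values were seen.

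The alternatives were other pseudocounts (0.5 and 10), no filter and a stricter filter, equal totals, quantile normalization, variance models without the trend or with robust estimation, library weights, fits of only the 2 genotypes compared, a replicate block, edgeR's quasi-likelihood test and DESeq2 on the recovered reads, an adjusted p of 0.10, a window of 20 Mb, and leaving out each library in turn. A correction for transcript length and GC content was added after the data had been seen. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were used.

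The limma steps were tested on simulated counts with the means, dispersions and depths of these libraries, in 5 datasets per comparison. Each dataset held 200 changed genes and a further set of genes with a smaller change. For Svil-KO against WT, 41.6% of genes changed 2-fold and 73.6% of genes changed 4-fold were called, over a mean of 14854 genes tested, and 3.97% of the calls were false. For Svil-Mut against WT the shares were 44.2%, 70.6% and 6.47% over 14853 genes, and for Svil-KO against Svil-Mut 42.2%, 71.8% and 6.39% over 14849 genes. These shares hold for that many changed genes and were not measured for fewer, as may be the case in Svil-KO against WT. No pair of libraries of 1 genotype agreed within sampling noise, with a mean chi-square per gene of 23.1 to 84, so each library counted as a separate replicate. With 3 against 3 libraries, an exact permutation test cannot give a p below 0.1.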

Results

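Supervillin, encoded by Svil, is an actin- and myosin-binding protein of the villin and gelsolin family that is found at the membrane skeleton and, in striated muscle, at costameres. The series concerns how mice with altered Svil respond to insulin, handle glucose and use their muscles, and the RNA data address what differs in the TA muscle of these mice. Gene expression was measured in 9 libraries, 3 per genotype, one from each 13-month-old male mouse. Depth was 36234428 to 48762188 reads per library. The 10 most abundant genes took 25.2% ± 0.58 of the counts in WT, 25.6% ± 1.1 in Svil-KO and 28.2% ± 0.58 in Svil-Mut (SD, n = 3). Transcripts of the mitochondrial genome took 5.98% ± 0.61, 6.23% ± 0.35 and 4.58% ± 0.58 of the counts in the same order (SD, n = 3). In a principal component analysis, the first component held 17.8% of the variance. The Svil-Mut libraries lay at 16.8 to 79.6 on it and the WT and Svil-KO libraries at -32.1 to -12.1. Svil-Mut replicate 2 (79.6) stood apart there, and Svil-Mut replicate 4 (-79.5) on the second component, which held 14.7%. The third, with 13%, set WT replicate 1 (-65.3) and WT replicate 3 (49.3) on opposite sides, so the WT libraries that both comparisons against WT share also spread.

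Svil itself (ENSMUSG00000024236.18, GRCm38 chromosome 18, 4920540 to 5119299, plus strand, protein coding) was measured first, as the altered gene. Its normalized count was 8822 ± 497 in WT, 6934 ± 407 in Svil-KO and 4379 ± 381 in Svil-Mut (SD, n = 3), and the libraries of the 3 genotypes did not overlap. Svil-Mut had 49.6% of the WT level (log2 fold change -1.01 ± 0.086 SE, limma adjusted p = 0.000941). Svil-KO had 78.6% of the WT level (log2 fold change -0.35 ± 0.086 SE, limma unadjusted p = 0.00207 for this gene taken alone). It did not pass over all genes tested (adjusted p = 0.997). The exact 2-sided permutation p was 0.1 for each pair of genotypes, the smallest that 3 against 3 libraries allow. The labels do not say which part of the gene is altered in either genotype, and counts over the whole gene do not show whether the remaining Svil transcripts were intact.

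**Figure D1:**
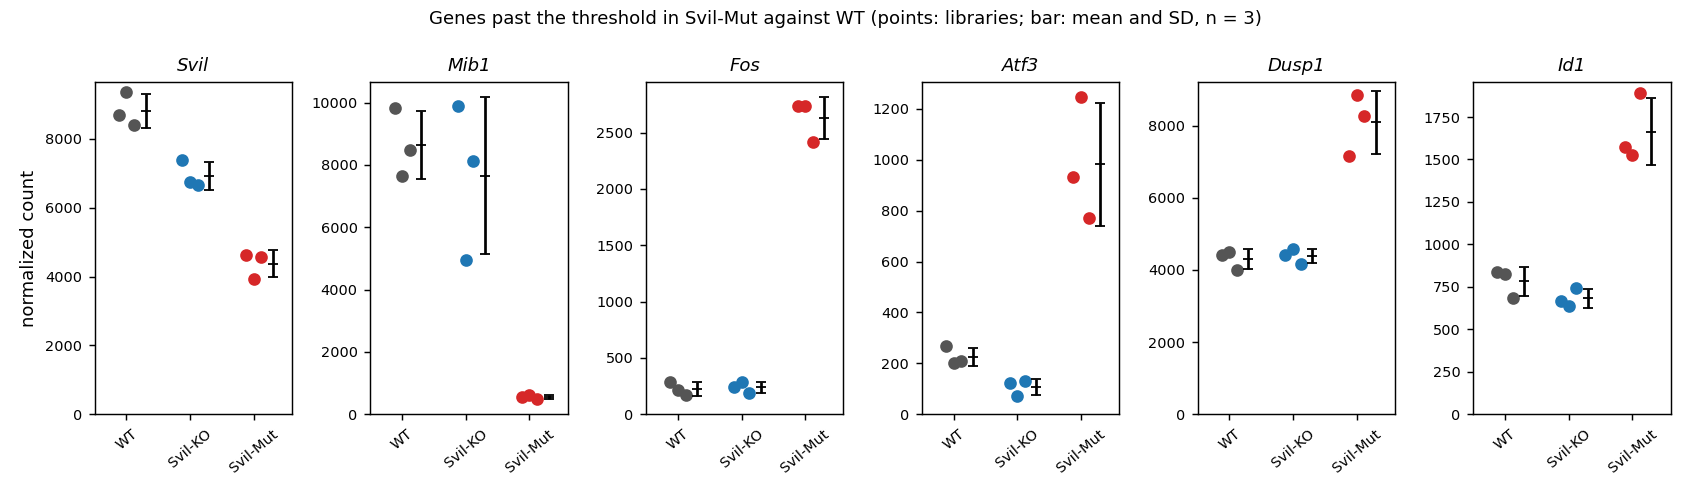
Normalized counts per library for the 6 genes past the threshold in Svil-Mut against WT, each on its own linear axis starting at 0, with points for libraries and bars for mean and SD (n = 3). Mib1 lies at 496 to 623 in the Svil-Mut libraries against 7634 to 9818 in WT, and Fos at 2418 to 2740 against 167 to 287.

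No gene passed the threshold in Svil-KO against WT. The smallest adjusted p was that of N4bp2, a protein with a polynucleotide kinase domain, at 143 ± 7.7 against 27.7 ± 8.0 normalized counts (SD, n = 3; log2 fold change 2.36 ± 0.30 SE, adjusted p = 0.151). Among the other genes with the smallest p, none of which passed, Col7a1, the collagen of anchoring fibrils, was at 132 ± 7.5 against 37.9 ± 15.5 (log2 fold change 1.84), and Bdnf, a neurotrophin, at 8.4 ± 7.2 against 63.8 ± 18 (log2 fold change -3.00). Camk1d, a calcium/calmodulin-dependent kinase (-2.49), Parp14, an ADP-ribosyltransferase (-1.01), and Atf3, a stress-induced transcription factor (-1.09), also had negative log2 fold changes. Phex (2.73), Stxbp2 (1.27) and Abca2 (0.72) had positive ones. The adjusted p was 0.95 for Col7a1 and 0.997 for the others named. By limma, 628 of the 15279 genes (4.11%) had an unadjusted p under 0.05, and 10.7% of genes had no overlap between the genotypes, where chance gives 10%. EdgeR also called 0 genes, and DESeq2 called 4, which were N4bp2, Col7a1, Bdnf and the predicted gene Gm9061, the last named only because DESeq2 called it.

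The lists that bear on the subject of the study did not pass in Svil-KO. The 40 genes from the insulin receptor to Akt and its brakes had a mean log2 fold change of 0.07 (adjusted p = 0.168) and the 28 glucose transporter and glycolysis genes one of -0.01 (adjusted p = 0.813), with a median of 0.01 and a test direction of higher, so mean and test differ in sign. Slc2a4, the insulin-responsive glucose transporter GLUT4, was at 30829 ± 1285 in Svil-KO and 28065 ± 1557 in WT (SD, n = 3; log2 fold change 0.14, adjusted p = 0.997). Of the 42 lists, 3 were lower by camera, the cytosolic ribosomal proteins (67 genes, mean log2 fold change -0.12, adjusted p = 7.73e-13), the nuclear-encoded respiratory chain (72 genes, -0.05, adjusted p = 0.000243) and the heat shock chaperones (23 genes, -0.17, adjusted p = 0.0077). Each of these has an adjusted p = 0.878 with an estimated correlation and an adjusted p = 0.933 by fry. No member of the 3 lists passed over all genes tested, and 0 passed adjusted over the list alone. The other 39 lists had adjusted p-values of 0.168 to 0.908. With the trend of transcript length and GC content removed, a step added after the data had been seen, the respiratory chain list was at -0.02 (adjusted p = 0.385), and relabelled splits of the same 6 libraries called up to 9 lists. The respiratory chain list lost its call without WT replicate 4 (adjusted p = 0.807) and the heat shock list without WT replicate 4 (adjusted p = 0.181) or Svil-KO replicate 1 (adjusted p = 0.0668). The respiratory chain mean was -0.0016 without WT replicate 4 and -0.08 without WT replicate 1. Without Svil-KO replicate 4, 5 lists were called and the ribosomal mean was -0.08, and without the variance trend the heat shock list lost its call (adjusted p = 0.0611).

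Svil-Mut muscle had higher immediate early transcripts and much lower Mib1. In Svil-Mut against WT, 6 genes changed, 4 higher and 2 lower. An unadjusted limma p under 0.05 was reached by 1533 of the 15279 genes (10%). No overlap between the genotypes was seen for 13.9% of genes, where chance gives 10%. Mib1, an E3 ubiquitin ligase of Notch ligands, fell 15.5-fold, from 8642 ± 1102 to 555 ± 64 normalized counts (SD, n = 3; log2 fold change -3.96 ± 0.21 SE, adjusted p = 2.64e-05). The other gene called lower was Svil. The antisense gene Mir133a-1hg (chromosome 18, 10781723 to 10785883) lies within Mib1, and the kit does not mark strand, so part of the Mib1 reads may stem from it. Its own log2 fold change was -0.44 (limma unadjusted p = 0.0447, adjusted p = 0.483). Fos, a subunit of the AP-1 transcription factor, rose from 222 ± 60 to 2630 ± 183 (SD, n = 3; log2 fold change 3.59 ± 0.21 SE, adjusted p = 3.45e-05). Atf3 rose by 2.10 on the log2 scale (adjusted p = 0.0184), Id1, an inhibitor of basic helix-loop-helix factors, by 1.09 (adjusted p = 0.0143) and Dusp1, a MAP kinase phosphatase, by 0.91 (adjusted p = 0.00428). The next genes by p did not pass: Csrnp1 and Nr4a1 had log2 fold changes of 2.70 and 1.55 (adjusted p = 0.0525), and Klf2 and Apold1 had 1.62 and 3.98 (adjusted p = 0.0531). EdgeR called 6 genes and DESeq2 called 176, 103 higher and 73 lower. Atf3 lost its call without WT replicate 3 (adjusted p = 0.127), WT replicate 4 (adjusted p = 0.157) or Svil-Mut replicate 2 (adjusted p = 0.0738), and Id1 without WT replicate 3 (adjusted p = 0.0639) or WT replicate 4 (adjusted p = 0.0932). With a variance model without the trend, Atf3 (adjusted p = 0.151), Id1 and Dusp1 (adjusted p = 0.129 each) and Svil (adjusted p = 0.0551) lost theirs, while Fos and Mib1 were called under all 24 alternatives run. The count was 17 without Svil-KO replicate 1, 12 without Svil-KO replicate 3, 18 without Svil-Mut replicate 1 and 13 without Svil-Mut replicate 4.

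The immediate early list rose as a group in Svil-Mut. All 25 tested members had positive log2 fold changes (mean 2.09, camera adjusted p = 1.72e-33). Its call was kept with an estimated correlation (adjusted p = 0.04), the only 1 of the 14 lists called in this comparison for which this held. By fry it was also the only 1 of the 42 lists to pass (adjusted p = 0.00372), and the other 13 called by camera had adjusted p = 0.155 to 0.529. Over all genes tested, 3 members passed (Fos, Dusp1 and Atf3), and 21 passed adjusted over the list alone, all higher. The list stood at 1.78 to 2.46 above the WT mean in the 3 Svil-Mut libraries, at 0.86 in Svil-KO replicate 1 and at -0.09 and -0.04 in the other Svil-KO libraries. Of the cell type markers, the red blood cell list was higher beside it (mean 1.56, camera adjusted p = 0.000341, adjusted p = 0.381 with an estimated correlation). None of its 8 members passed over all genes or adjusted over the list alone, and its levels in the Svil-Mut libraries spread from 0.35 to 2.99, with a mean of 0.84 without Svil-Mut replicate 4.

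**Figure D2:**
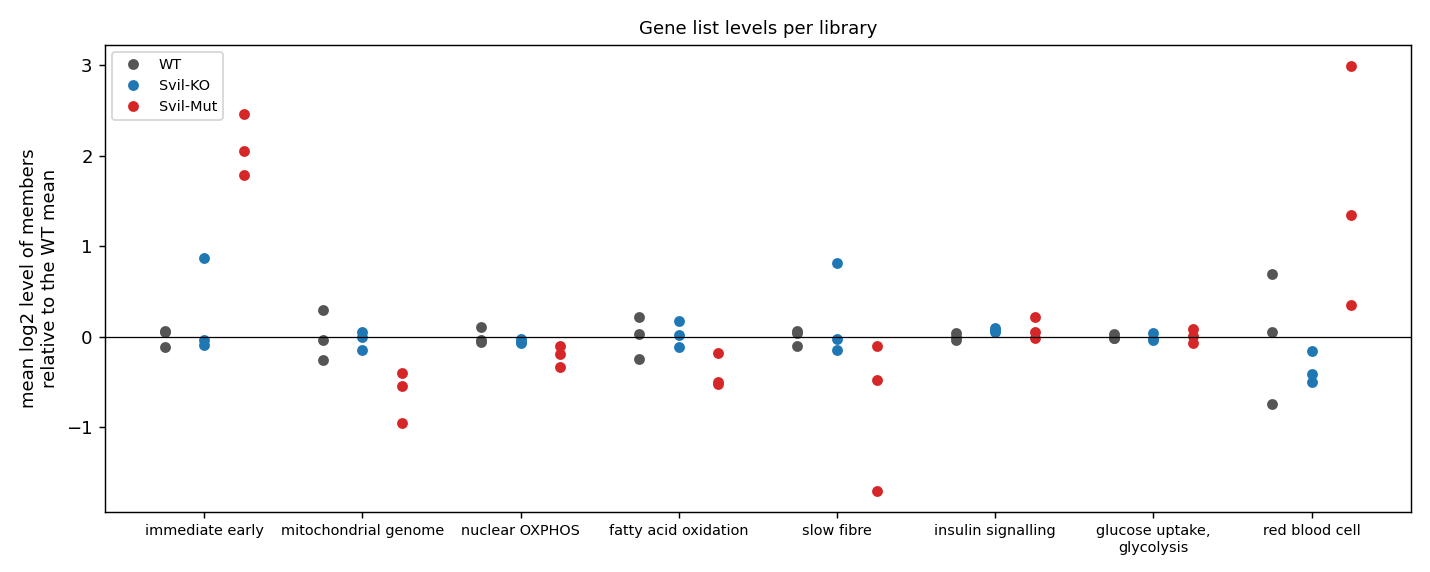
Mean log2 level of the tested members of 8 gene lists in each library, relative to the WT mean of each gene, with 1 point per library. The immediate early lists of the 3 Svil-Mut libraries lie at 1.78 to 2.46, above every WT and Svil-KO library, while insulin signalling lies at -0.04 to 0.21 over the 9 libraries.

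Lists of mitochondrial energy metabolism were lower in Svil-Mut by camera with the preset correlation. The 72 nuclear-encoded respiratory chain genes had a mean log2 fold change of -0.21, each of them below 0 (adjusted p = 3.79e-29, and adjusted p = 0.345 with an estimated correlation). None passed over all genes tested, and 35 passed adjusted over the list alone, among them Ndufb9 (-0.31), Cox5b (-0.33), Uqcrq (-0.38) and Ndufb6 (-0.29). The 13 protein genes of the mitochondrial genome averaged -0.63 (adjusted p = 4.14e-11, and adjusted p = 0.345 with an estimated correlation), with 0 passing over all genes and 10 adjusted over the list alone. The pyruvate and citric acid cycle list averaged -0.23 (adjusted p = 1.31e-10, and adjusted p = 0.345 with an estimated correlation), with 0 and 13 members passing, 12 of the 13 lower. In it, Pdk4, a kinase that inhibits pyruvate dehydrogenase, was at 9150 ± 2885 against 36483 ± 17860 (SD, n = 3; log2 fold change -1.91, adjusted p = 0.279 over all genes). Fatty acid oxidation averaged -0.40 (adjusted p = 1.94e-11, and adjusted p = 0.37 with an estimated correlation), with 0 and 12 members passing, and Cpt1a, which admits fatty acids to mitochondria, had a log2 fold change of -0.96. The slow fibre list averaged -0.76 (adjusted p = 0.000186, and adjusted p = 0.446 with an estimated correlation), with 0 and 5 members passing. Its member Mb, myoglobin, had a log2 fold change of -1.06. The level of this list was -1.70 in Svil-Mut replicate 2 and -0.11 in Svil-Mut replicate 4, and without Svil-Mut replicate 2 its mean was -0.29 and its call was lost (adjusted p = 0.063). Adipocyte markers (mean -1.20, median -0.31, adjusted p = 0.00908) and fibro-adipogenic markers (-0.29, adjusted p = 0.04) were lower too, with adjusted p = 0.446 and adjusted p = 0.51 with an estimated correlation. The adipocyte level was -1.61 and -2.34 in Svil-Mut replicates 1 and 2 and 0.35 in replicate 4, and its call was lost without replicate 1 (adjusted p = 0.0806) or replicate 2 (mean -0.63, adjusted p = 0.18), while without replicate 4 the mean was -1.97. It was also lost by edgeR (mean -0.76, adjusted p = 0.0502), by DESeq2 (-0.77, adjusted p = 0.0529) and with only genes of a mean of at least 50 (-0.57, adjusted p = 0.128), and the mean was -0.66 with a pseudocount of 10. The call of the fibro-adipogenic markers was lost without WT replicate 3 (mean -0.10, adjusted p = 0.646) or Svil-Mut replicate 2 (-0.18, adjusted p = 0.509), and with equal totals, quantile normalization, no variance trend, library weights, only 2 genotypes in the fit, edgeR or DESeq2 (adjusted p = 0.0502 to 0.0865). No marker of either list passed over all genes or adjusted over the list alone.

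Besides the immediate early and red blood cell lists, 5 lists were higher in Svil-Mut by camera. They were the circadian clock (mean 0.31, adjusted p = 0.000186), ER stress (0.10, adjusted p = 0.000511), cell cycle arrest and p53 targets (0.37, adjusted p = 0.0019), calcium handling (0.06, adjusted p = 0.00587) and inflammation (0.73, median 0.29, adjusted p = 0.00705). With an estimated correlation the calcium list had an adjusted p = 0.491 and the other 4 an adjusted p = 0.345. No member of the 5 passed over all genes tested. Adjusted over the list alone, 5 clock genes passed, led by Bhlhe40 (log2 fold change 0.84) and Arntl (0.85), 2 ER stress genes, Ppp1r15a (0.67) and the chaperone Hspa5 (0.42), and 4 of the p53 list, led by Btg2 (2.37) and Cdkn1a (1.07). None of the calcium or inflammation genes did. Btg2 is also a member of the immediate early list, so the p53 list is not separate from that list. Calls were lost without Svil-Mut replicate 2 for calcium handling (adjusted p = 0.179), without Svil-Mut replicate 4 for ER stress and inflammation (adjusted p = 0.0635 each) and without WT replicate 4 for inflammation (adjusted p = 0.0761). The ER stress level was -0.09, 0.08 and 0.32 in Svil-Mut replicates 1, 2 and 4, and the mean of that list was -0.0076 without replicate 4, 0.20 without replicate 1 and 0.05 without WT replicate 1 or with library weights. The calcium mean was 0.04 without WT replicate 4 and 0.03 without a filter or with equal totals. The inflammation mean was 0.45 with a pseudocount of 10, and 0.30 with only genes of a mean of at least 50, where its call was lost (adjusted p = 0.119). Insulin signalling (mean 0.08, adjusted p = 0.324) and glucose uptake with glycolysis (0.01, median -0.01, adjusted p = 0.848) did not pass. Adjusted over the list alone, 1 member of each did, Irs2, an insulin receptor substrate, at 3733 ± 1764 against 1069 ± 84 (SD, n = 3; log2 fold change 1.66, adjusted p = 0.182 over all genes), and Slc2a1, the glucose transporter GLUT1, with a log2 fold change of 0.68 (adjusted p = 0.213 over all genes). Across the 28 lists that did not pass, adjusted p ran from 0.0512 to 0.989. Relabelled splits of the same 6 libraries called up to 16 lists, against 14 in the real one.

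Svil-KO and Svil-Mut differed from each other in 7 genes. An unadjusted limma p under 0.05 was reached by 1556 of the 15279 genes (10.2%), and 15.2% of genes had no overlap, where chance gives 10%. Mib1 (log2 difference 3.73 ± 0.21 SE, adjusted p = 4.78e-05) and Svil (0.67 ± 0.086 SE, adjusted p = 0.0261) were higher in Svil-KO. Fos (-3.48, adjusted p = 4.78e-05), Atf3 (-3.19, adjusted p = 0.000628), Id1 (-1.28, adjusted p = 0.00375), Dusp1 (-0.88, adjusted p = 0.0047) and Klf4, a zinc finger transcription factor (-2.28, adjusted p = 0.0261), were lower in Svil-KO. Kif5b, a kinesin heavy chain (-0.68, adjusted p = 0.0623), Lrrc32 (-1.80, adjusted p = 0.0845) and Nav3 (3.39, adjusted p = 0.0845) came next and did not pass. EdgeR called 7 genes and DESeq2 216. The Svil call was lost when any of WT replicates 1 and 4, the 3 Svil-KO replicates or Svil-Mut replicate 2 was left out, with adjusted p up to 0.11. The Klf4 call was lost without WT replicate 1 or 4, Svil-KO replicate 3 or 4, or Svil-Mut replicate 2 or 4, with adjusted p up to 0.142, and that of Dusp1 without Svil-KO replicate 4 (adjusted p = 0.0511). Without the variance trend, Id1 (adjusted p = 0.0532), Dusp1 (adjusted p = 0.161), Klf4 (adjusted p = 0.235) and Svil (adjusted p = 0.321) lost their calls, and with only these 2 genotypes in the fit Klf4 and Svil did (adjusted p = 0.107 each). The count was 13 without Svil-KO replicate 1 and 4 without Svil-KO replicate 4.

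By camera, 18 lists differed between Svil-KO and Svil-Mut, 7 higher and 11 lower in Svil-KO. The immediate early list was lower in Svil-KO in all 25 members (mean -1.85, adjusted p = 1.55e-30, and adjusted p = 0.051 with an estimated correlation), with 4 members passing over all genes and 21 adjusted over the list alone. Higher in Svil-KO were slow fibre (0.97), the mitochondrial genome (0.60), tenocyte markers (0.46), fatty acid oxidation (0.43), pyruvate and citric acid cycle (0.24), mitochondrial biogenesis (0.17) and the nuclear-encoded respiratory chain (0.16). Lower were red blood cell markers (-1.92), inflammation (-0.75), heat shock chaperones (-0.48), p53 targets (-0.27), circadian clock (-0.22), ribosomal proteins (-0.14), the interferon response (-0.12), ER stress (-0.08) and calcium handling (-0.06). The fast fibre list was called lower with a mean of 0.02 and a median of -0.14, so its mean and its test differ in sign. With an estimated correlation none of the 18 passed, and apart from the immediate early list their adjusted p ran from 0.393 to 0.537. By fry the immediate early list passed (adjusted p = 0.00521) and the other 17 did not (adjusted p = 0.181 to 0.478). Relabelled splits of the 6 libraries called up to 17 lists. No member outside the immediate early list passed over all genes, except 1 of the growth factor list, which was not called. Adjusted over the list alone, 16 pyruvate and citric acid cycle, 11 fatty acid oxidation, 10 mitochondrial genome and 2 slow fibre genes passed, all higher in Svil-KO, and 8 heat shock, 7 ER stress and 5 red blood cell genes, all lower. Leaving out Svil-Mut replicate 2 took slow fibre to 0.50 and heat shock to -0.28, and leaving out Svil-Mut replicate 4 took the respiratory chain to 0.095, ribosomal proteins to -0.073 and red blood cell markers to -1.20, with their calls kept at the preset correlation. Other lists lost their calls without 1 library or another: tenocyte markers (Svil-KO replicates 1 and 4, Svil-Mut replicates 2 and 4, adjusted p up to 0.586), p53 targets (Svil-KO replicate 3, Svil-Mut replicates 2 and 4, up to 0.22), the clock (Svil-KO replicates 3 and 4, Svil-Mut replicate 4, up to 0.263), mitochondrial biogenesis (Svil-KO replicate 1, Svil-Mut replicate 4, up to 0.119), fast fibre (Svil-KO replicate 4, Svil-Mut replicate 2, up to 0.304), calcium handling (Svil-KO replicate 4, 0.0673) and the interferon response (Svil-Mut replicate 4, 0.56). The tenocyte mean was 0.12 and 0.19 without Svil-KO replicate 1 and Svil-Mut replicate 2, and 0.78 without Svil-KO replicate 3 or Svil-Mut replicate 1. The p53 mean was -0.17 without Svil-KO replicate 3 and the clock mean -0.145 without Svil-KO replicate 4, while the calcium mean was -0.0085 without Svil-KO replicate 4 and -0.10 without Svil-KO replicate 1. The interferon mean was 0.12 without Svil-Mut replicate 4, -0.19 and -0.29 without Svil-Mut replicates 1 and 2, and -0.24 without WT replicate 1 or 4. The ER stress mean was -0.18 without Svil-Mut replicate 1 and 0.03 without Svil-Mut replicate 4, where its test still called it lower (adjusted p = 0.0258). With calls kept, it was -0.028 with library weights, -0.05 without a filter and -0.17 with only genes of a mean of at least 50. Likewise, the interferon mean was -0.053 with library weights, -0.062 by edgeR and -0.236 with a mean of at least 50. The fast fibre mean was -0.01 to 0.05 with 1 library left out, and below 0 without Svil-KO replicate 1 or Svil-Mut replicate 2, by edgeR and by DESeq2. With only genes of a mean of at least 50, inflammation (-0.33, adjusted p = 0.0648), tenocyte markers (0.26, adjusted p = 0.0998) and fast fibre (adjusted p = 0.0506) lost their calls, and the inflammation mean was -0.47 with a pseudocount of 10. Without the variance trend, tenocyte markers (adjusted p = 0.0834), mitochondrial biogenesis (adjusted p = 0.0503) and the clock (adjusted p = 0.0552) lost theirs, and with library weights tenocyte markers (adjusted p = 0.0525), the clock (adjusted p = 0.0842) and p53 targets (adjusted p = 0.0653) did. Tenocyte markers also lost theirs with equal totals (adjusted p = 0.0571), fast fibre with quantile normalization (adjusted p = 0.09) and mitochondrial biogenesis with the length and GC trend removed (adjusted p = 0.0881). The other 24 lists had adjusted p-values of 0.0736 to 0.984.

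No gene passed in both comparisons against WT. Across genes, the 2 sets of log2 fold changes had a Pearson correlation of 0.458, where unchanged groups simulated against the same 3 WT libraries gave 0.503 ± 0.012 (SD of 100 simulations). Their covariance was 0.149 against a simulated 0.132 ± 0.0045, and 63.5% of genes had the same sign against 66.8%. The correlation and the same-sign share thus lay below the simulated means and the covariance above. The simulated groups had no changed genes, unlike Svil-Mut, so these measures do not decide whether a response is shared. The overlap of independent lists is 0 in either direction because Svil-KO has no calls. Genes are not independent replicates, and with 3 WT libraries the controls could not be split.

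Genes close to Svil on chromosome 18 differed in Svil-Mut more often than other genes. Within 10 Mb, 2 of 52 tested genes passed in Svil-Mut against WT, Svil and Mib1 (10725548 to 10818704), compared with 4 of 15227 elsewhere (Fisher's exact p = 0.000169). Without Svil it was 1 of 51 (Fisher's exact p = 0.0166). At an unadjusted p under 0.01, a level chosen after the data had been seen, it was 8 of 51 genes without Svil (15.7%) against 2.79% elsewhere. Of these 8, Abhd3 (log2 fold change 2.23), Cables1 (1.46), Kif5b (0.64), Impact (0.64) and Riok3 (0.36) had positive and Mib1 (-3.96), Tmem241 (-0.95) and Npc1, a cholesterol transporter (-0.78), negative values. Of the 8, 7 lay between Abhd3, which starts at 10642092, and Impact, which ends at 12992950. In Svil-KO against WT, 0 of the same 51 genes reached that level, against 0.624% of genes elsewhere. Mib1 was at 7654 ± 2512 in Svil-KO (SD, n = 3), with a log2 fold change against WT of -0.23 (adjusted p = 0.997). In Svil-KO against Svil-Mut, 2 of the 52 genes passed, compared with 5 elsewhere (Fisher's exact p = 0.000236). Without Svil it was 1 of 51 (Fisher's exact p = 0.0199). Without WT replicate 1 or 4, any Svil-KO replicate or Svil-Mut replicate 2, 1 gene passed there, with a Fisher's exact p of up to 0.043.

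**Figure D3:**
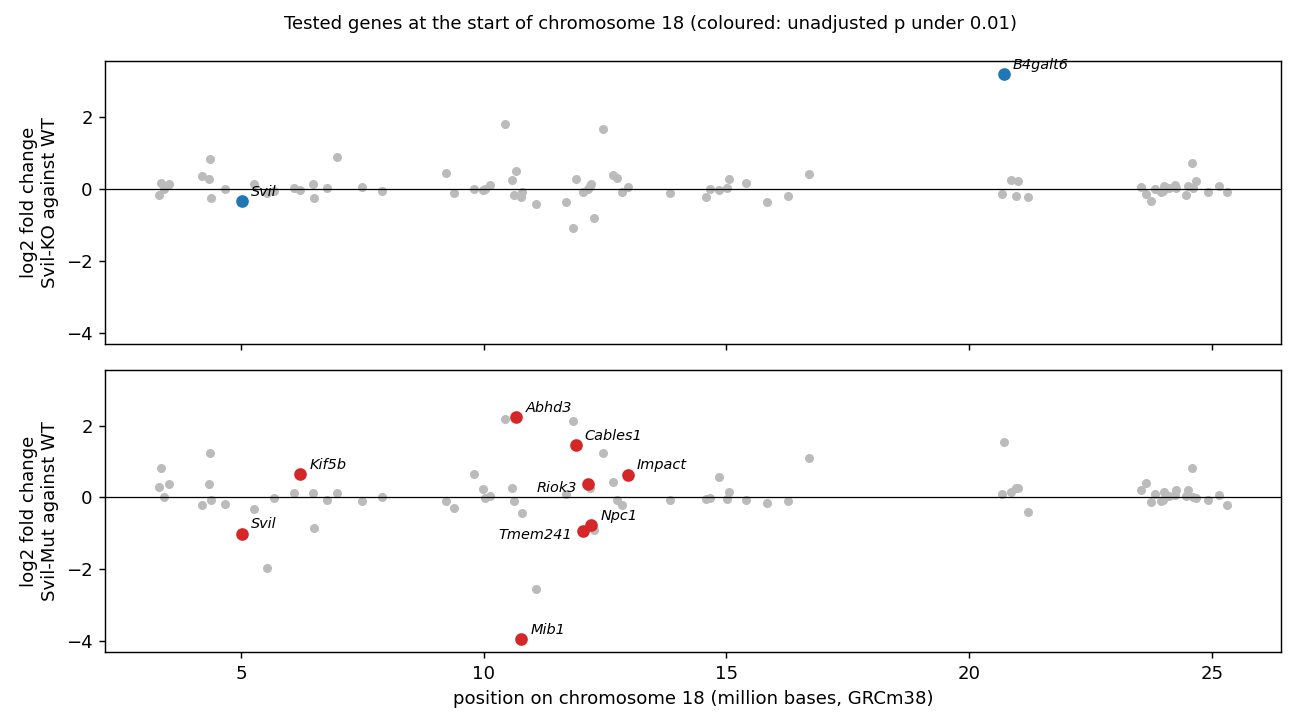
Log2 fold change against WT of each tested gene up to 30 Mb on chromosome 18 (GRCm38, position in Mb), for Svil-KO above and Svil-Mut below, with coloured and named points for an unadjusted p under 0.01. In Svil-Mut, Svil, Kif5b and a group from Abhd3 to Impact are coloured, with Mib1 at -3.96, and in Svil-KO only Svil and B4galt6 are.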

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

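The comparison of Svil-KO with Svil-Mut and the leaving out of libraries were planned, and the tests of splits, of genes near Svil at an unadjusted p under 0.01, of marker lists, of tissue collection and of length and GC content, and the use of left-out libraries to weigh an explanation, were chosen after the results had been seen. That comparison tests whether the effects of the 2 genotypes against WT differ, and it marked 7 genes and 18 lists. The log2 differences, Svil-KO minus Svil-Mut, were 3.73 for Mib1 and 0.67 for Svil, and -3.48 for Fos, -3.19 for Atf3, -2.28 for Klf4, -1.28 for Id1 and -0.88 for Dusp1. The mean differences of the lists were 0.97 for slow fibre, 0.60 for the mitochondrial genome, 0.46 for tenocyte markers, 0.43 for fatty acid oxidation, 0.24 for pyruvate and citric acid cycle, 0.17 for mitochondrial biogenesis, 0.16 for the nuclear-encoded respiratory chain and 0.016 for fast fibre. They were -1.92 for red blood cell markers, -1.85 for immediate early genes, -0.75 for inflammation, -0.48 for heat shock chaperones, -0.27 for p53 targets, -0.22 for the circadian clock, -0.14 for ribosomal proteins, -0.12 for the interferon response, -0.080 for ER stress and -0.056 for calcium handling. With an estimated correlation none of the 18 lists passed, with adjusted p = 0.051 for the immediate early genes and 0.393 to 0.537 for the others.

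Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. For Svil-Mut against WT the real split gave 6 genes and the highest other split 0, so 1 of 10 splits gave as many. For Svil-KO against Svil-Mut the real split gave 7 and the highest other 0, again 1 of 10, and for Svil-KO against WT every one of the 10 splits gave 0. List calls were a different matter. In Svil-Mut against WT, 4 of 10 splits called as many lists as the real one (14, highest other 16), in Svil-KO against WT 9 of 10 did (3, highest other 9), and in Svil-KO against Svil-Mut 1 of 10 did (18, highest other 17). Each mixed split still sets 2 libraries of a genotype against 1, and the preset correlation of 0.01 lies below estimates such as 0.71 for the respiratory chain in Svil-KO against WT. What the mixed splits call was not traced to either.

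The 51 genes within 10 Mb of Svil, Svil left out, differed in Svil-Mut more often than placement by chance along the genome gives (Fisher's exact p = 8.53e-05 for an unadjusted p under 0.01). Reads lost over strain variants in the Svil-Mut libraries would lower genes there and make none higher. Yet 5 of the 51 genes (9.8%) were higher at that level against 1.41% elsewhere (Fisher's exact p = 0.000794). That argues against reads lost in the Svil-Mut libraries as the whole cause. It does not address reads lost in the WT libraries, which would act in the opposite direction. For the 3 that were lower, Mib1 among them, lost reads and lower expression cannot be told apart, because no reads were analysed here. A candidate explanation is a chromosome segment or second alteration carried with the Svil-Mut allele, which may affect genes from Abhd3 to Impact apart from any effect of supervillin. The genotype itself also stays open, since every Svil-Mut mouse carries the allele and its neighbourhood together.

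Immediate early genes were higher in Svil-Mut, and a single library does not account for it, since the largest adjusted p after leaving out any 1 Svil-Mut library was 2.05e-28. Marker lists of 8 other nucleated types lay below the 2.10 of the immediate early genes by at least 2.18 of their own SD between libraries. For types with a narrow spread, such as endothelial cells (-0.02 ± 0.16, SD, n = 3), this argues against more cells as the cause. Adipocyte (-1.2 ± 1.4), macrophage (0.05 ± 0.94) and lymphocyte markers (0.35 ± 0.97) spread too widely for their means to decide. In Svil-Mut replicates 1 and 2, whose immediate early levels were 2.05 and 2.46, macrophage markers were at -0.565 and -0.418. Lymphocyte markers were at -0.62 and 0.367 there, and adipocyte markers at -1.61 and -2.34. In replicate 4, whose immediate early level was 1.78, macrophage, lymphocyte and adipocyte markers were at 1.13, 1.31 and 0.348. Red blood cell markers, higher in Svil-Mut (1.56 ± 1.3), were left out of this check, and cell types without a list were not covered. Immediate early genes respond within minutes to handling and killing, so a difference in how or when muscles were collected may also produce the pattern. Their level in Svil-KO replicate 1 stood 0.86 above the WT mean while the other 2 Svil-KO libraries did not, so the level also varied within a genotype. The circadian clock list, also higher in Svil-Mut at the preset correlation, was at 0.225 to 0.414 there and at -0.0627 to 0.258 in Svil-KO. Either the hour of collection or the genotype may underlie this. Collection and genotype cannot be told apart here, because the labels give no collection times or order.

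4 mitochondrial lists were lower in Svil-Mut at the preset correlation, and all 4 calls were lost with an estimated correlation (adjusted p = 0.345 for 3 lists and adjusted p = 0.37 for fatty acid oxidation). Transcript length and GC content account for little of the lower means. Their fitted trend explained 0.0614% to 0.847% of the variance in a library. With it removed, the nuclear-encoded respiratory chain averaged -0.19 against -0.21 before, and the mitochondrial genome -0.57 against -0.63. Fatty acid oxidation was at -0.398 against -0.403, and pyruvate and citric acid cycle at -0.229 both times. The largest camera adjusted p over the 4 lists was then 3.69e-10. Leaving out a single Svil-Mut library did not end the calls, with a largest camera adjusted p over the 4 lists of 7.76e-07. These p-values use the preset correlation, and 4 of the 10 splits called as many lists, so variation shared by the members of a list stays open beside the genotype.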

How the results depend on the processing

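The length and GC correction and the window without Svil were chosen after seeing the data. The replicate numbers are not said to pair the mice, so pairing is unknown. Same-numbered Svil-KO and WT libraries had correlations of 0.026, 0.044 and 0.038, and each Svil-KO library correlated best with its own number, which is a hint from the data only. Svil-Mut replicates 1 and 4 had 0.0071 and -0.056 with the WT libraries of the same number. Only Svil-Mut has a replicate numbered 2, so a replicate block gives that library its own term and takes it out of every comparison. Values with the block thus also reflect its loss, as for heat shock in Svil-KO against Svil-Mut (-0.274 with the block, -0.275 without Svil-Mut replicate 2). With the block, Svil-KO against WT gave 0 genes, Svil-Mut against WT 7, 3 of them among the 6 called without it, and Svil-KO against Svil-Mut 6, 3 of them among the 7. Not called with the block were Atf3 (adjusted p = 0.0781), Id1 (0.11) and Dusp1 (0.0649) in Svil-Mut against WT, and Id1 and Dusp1 (0.0695 each), Klf4 (0.147) and Svil (difference 0.58, adjusted p = 0.148) in Svil-KO against Svil-Mut. With the block 3, 17 and 15 lists were called in Svil-KO against WT, Svil-Mut against WT and Svil-KO against Svil-Mut. Not called with it were adipocyte (-0.61, adjusted p = 0.109) and fibro-adipogenic markers (-0.13, adjusted p = 0.771) in Svil-Mut against WT, and fast fibre (-0.018, adjusted p = 0.205), p53 targets (-0.155, adjusted p = 0.111) and tenocyte markers (0.23, adjusted p = 0.358) in Svil-KO against Svil-Mut. Slow fibre was at -0.37 and 0.58 in these comparisons, and heat shock at -0.27 and interferon at -0.30 in the latter, all still called. Near Svil, 1 gene was called in Svil-KO against Svil-Mut (Fisher's exact p = 0.0203). The correlation of the fold changes was 0.412 with it.

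The number of genes changed in Svil-Mut against WT was 19 with a pseudocount of 10, 16 with a mean of at least 50, 16 with robust estimation, 14 with only 2 genotypes in the fit, 20 at an adjusted p of 0.10, 176 by DESeq2, and 4 to 18 when 1 library was left out (17 without Svil-KO replicate 1, 12 without Svil-KO replicate 3, 18 without Svil-Mut replicate 1, 13 without Svil-Mut replicate 4). Svil-KO against Svil-Mut gave 19 genes at 0.10, 216 by DESeq2, and 4 to 13 when 1 library was left out (13 without Svil-KO replicate 1, 4 without Svil-KO replicate 4). Svil-KO against WT gave 4 by DESeq2 and 0 under the others. The cause of the larger DESeq2 counts was not tested. DESeq2 called 2 genes in both comparisons against WT. Without the trend, 2 of the 6 calls in Svil-Mut against WT and 3 of the 7 between Svil-KO and Svil-Mut were made again, and Svil was at -1.01 in Svil-Mut (adjusted p = 0.0551) and 0.67 between Svil-KO and Svil-Mut (adjusted p = 0.321), and 0.67 with only 2 genotypes in the fit (adjusted p = 0.107). Leaving out 1 library gave 0.59 to 0.705. With an estimated correlation, 0, 1 and 0 lists were called in Svil-KO against WT, Svil-Mut against WT and Svil-KO against Svil-Mut. Leaving out 1 library gave 2 to 5 lists in Svil-KO against WT, 5 without Svil-KO replicate 4. The correlation was 0.419 with a pseudocount of 10, 0.482 without a filter, 0.382 with a mean of at least 50, 0.443 by edgeR and 0.4 to 0.571 when 1 library was left out.

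Of 3822 values of named genes under alternatives, 3690 kept their direction and side of the threshold, 106 newly passed, 25 no longer passed and 1 reversed: Col3a1 in Svil-Mut was -0.78, and -1.21 to 0.0063 when 1 library was left out, the last without Svil-Mut replicate 4. Only genes called in the main fit could lose a call, so the 25 losses fall on few of those named. Atf3 lost its call in Svil-Mut against WT under 5 of 24 alternatives and Klf4 between Svil-KO and Svil-Mut under 9, while Fos and Mib1 lost none. Of 875 list values, 783 kept their call and 92 lost it. The causes were not tested. The count of called genes near Svil stayed on its side of the threshold under all 26 alternatives in each comparison, with counts of 1 to 7 in Svil-Mut against WT (7 by DESeq2) and 1 to 6 in Svil-KO against Svil-Mut (6 by DESeq2).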

Other observations

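The lists tested here were chosen before the results were seen, and the DESeq2 values of N4bp2 and Col7a1 were singled out after. A few structural and developmental genes stood out in Svil-Mut within their lists. None of these passed over all genes tested. Adjusted over the list alone, 5 of the 30 shared sarcomere genes passed, among them Myom3, an M-band protein (146 ± 79 against 722 ± 143 normalized counts, SD, n = 3, log2 fold change -2.46, adjusted p = 0.0531 over all genes), Cryab, a small heat shock protein (-0.57), Csrp3, a Z-disc protein (-2.64), and Acta1, skeletal muscle actin (0.33). The list as a whole did not pass (adjusted p = 0.848, mean -0.20, median 0.03). Csrp3 is also a member of the slow fibre list and Cryab of the heat shock list. The slow fibre list was at -1.70 in Svil-Mut replicate 2 and at -0.107 in Svil-Mut replicate 4. The cytoplasmic actins Actg1 (0.93) and Actb (0.51) were the 2 members of the supervillin family and partner list that passed adjusted over the list alone (list adjusted p = 0.779, mean -0.03, median 0.03). In the list of regenerating fibres, Myod1 had a log2 fold change of 0.62 and Mest 1.22, and both passed adjusted over the list alone. So did Calcr, the calcitonin receptor of quiescent satellite cells, listed at 0 in the 3 Svil-Mut libraries and at 25.5 ± 20.6 in WT (SD, n = 3). The list had a mean of -0.29 and a median of 0.02, and was tested as higher (adjusted p = 0.989).

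N4bp2 and Col7a1, which had the largest and next largest statistics in Svil-KO, lay on the same side of WT in Svil-Mut. N4bp2 was at 73.5 ± 8.0 in Svil-Mut against 27.7 ± 8.0 in WT and Col7a1 at 112 ± 15 against 37.9 ± 15.5 (SD, n = 3), with limma adjusted p = 0.217 and adjusted p = 0.163. DESeq2 called both in each genotype, with adjusted p = 0.0136 for N4bp2 and adjusted p = 0.00389 for Col7a1 in Svil-Mut. Both comparisons share the same 3 WT libraries.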
